A study of Zea mays with 10 samples.

How the data were processed

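Total RNA from the stems of 5 inbred maize lines was labelled with biotin and hybridised to the Affymetrix maize array, per the labels. Each line had 2 arrays, and each array held the RNA of 1 pool of 5 untreated plants. The labels call the pools repetitions and say nothing of separate plots, so the p-values measure the spread between pools, which may be partly technical. The series design text speaks of an organ comparison, but every sample label gives stem, and the samples were therefore grouped by line only.

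The deposited table held 1 value per probe set and array on a log2 scale, made by the submitters with GCRMA, per the submitters' processing notes. GCRMA adjusts the background by probe sequence, normalizes the arrays to each other and summarises the probes of each probe set. The notes state no GCRMA version, the log2 scale was read from the range of the values (1.35 to 14.6), and scanner settings were not given in the sources used here. No further normalization was applied. GCRMA makes arrays alike in their distribution, so a shift of all genes in 1 line would have been removed, and it draws dim probe sets towards a common floor near 2. Folds that involve a line with a mean log2 value under 4 are therefore printed as at least so many fold. For a gene higher in 1 line, each other line under 4 was set to 4 before the mean of the others was taken. For a gene lower in 1 line, that line was set to 4 where it was under it. The number of arrays limits the precision of every value.

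The table held 17734 probe sets. The 113 array control probe sets were left out, and 66 reporter control probe sets were kept, of which 1 passed the filter. Probe sets with a log2 value of at least 4 on 2 or more arrays were tested, which left 11067. The annotation used here named 1 gene for 1452 probe sets, several genes for 1 and none for 16102, so most probe sets differ between lines without a gene name here. It named 1108 genes, of which 1060 were matched by gene identifier to the reference gene table of the B73 maize assembly (version 5.0), and 972 had a readable name. Gene names in the text are symbols or synonyms of that table. Among tested probe sets, 973 carried 1 of 814 genes. For a gene with several probe sets, the one with the highest mean over all arrays stood for it.

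Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), with all 10 arrays in 1 fit, line as the only term and no replicate block. The fit had 5 residual degrees of freedom and a prior of 3.09. All lines share 1 estimate of the spread of a probe set. Lines at the floor hardly vary, so the p-value of a gene bright in 1 line alone can understate the spread between its pools. A moderated F-test compared the 5 lines, 5 contrasts set each line against the unweighted mean of the other 4, and 10 contrasts compared lines in pairs. The F-test and every single contrast were each adjusted over probe sets by the Benjamini-Hochberg method, with no adjustment across contrasts. A probe set passed the threshold at an adjusted p under 0.05. Every adjusted p for a gene in the text comes from this limma fit, except where an omitted array or another setting is named beside it. A contrast against a mean of 4 lines also counts genes that stand out in only 1 of the 4, so the number of probe sets apart from each of the other 4 lines in pairwise contrasts is given beside it. A fold is against the mean log2 value of the other 4 lines and can rest on 1 of them. For genes higher in a line where some of the other lines, but not all, were under 4, the pairwise difference from the nearest line is given. It is printed for only part of the other genes, and a gene named without it may be close to another line. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

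Gene lists were tested with camera in limma at the preset correlation of 0.01, which asks whether the genes of a list rank higher or lower than other genes, with adjustment over all lists and lines. Camera with an estimated correlation and fry stood beside it. Fry tests whether the genes of a list move, on balance, one way and does not compare them with other genes. Lists with fewer than 5 tested genes have counts only. Topics and rules of the lists were set before the data were examined, but not this minimum of 5, which was set later. The annotation gives symbols but no descriptions, so members were chosen by symbol after the annotation and the number of calls were known, and before the values of any listed gene were looked at. At that stage a list of transport genes was divided into aquaporins and tubulins, lists of glutathione S-transferases and MADS-box genes were added, and a clock list without members was dropped. The 21 lists were lignin monomer biosynthesis; laccases and class III peroxidases; cellulose synthases and COBRA-like proteins; nucleotide sugar and hemicellulose enzymes; expansins and xyloglucan endotransglycosylase; structural wall proteins; MYB, NAC and KNOTTED-type regulators. The others were photosynthesis, cell division, flavonoid and anthocyanin genes, sucrose and starch metabolism, heat shock, auxin and gibberellin, aquaporins, tubulins, cytosolic ribosomal proteins, and brown midrib genes. Also tested were defence, jasmonate and benzoxazinoid genes, glutathione S-transferases, MADS-box genes, and pollen, tassel and seed genes.

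Genes were named by a rule set before the data were examined, apart from its condition of a described gene, which became a condition of a readable name. For each line, candidates had passed the threshold and had both arrays above, or both below, all 8 arrays of the other lines. From them came the 8 genes with the largest increase and the 8 with the largest decrease, and up to 3 higher and 3 lower members of each list. The condition on the arrays was at first left out for list members and was put back after the longer selection had been seen. The brown midrib gene bm1 was named regardless. The brown midrib genes bm2, bm3 and bm4 are not named by a probe set in the annotation used and were not analysed here.

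The procedure was tested on simulated data of 11067 probe sets, 200 of them changed in F7025. The noise was independent between arrays and had the spread that the fit of all lines gave each probe set. It recovered 20.9% of changes of 0.5 log2, 67.2% of changes of 1 and 93.9% of changes of 2, with 7 false calls among 128. With no change simulated, the F-test made 0 calls. In the real F7025 contrast 37.4% of probe sets passed, a far larger share than was changed here. Deviations shared between arrays were not simulated. These rates therefore describe the simulation and may differ in the data.

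Alternatives were no filter, a filter at 6, no variance trend, a robust variance prior, median centring, quantile normalization, a floor at 4, array weights, the replicate number as a block, and each array left out in turn. Further ones were contrasts fitted on the 4 arrays of 2 lines alone, the probe sets apart from each of the other lines, all probe sets of a gene in the list tests, and an estimated correlation. Chosen after seeing the data were list tests with no minimum size, the fit without the reporter control probe sets and the fit without the 3 arrays made from the least extracted RNA.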

Results

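Stem RNA of 5 inbred maize lines was profiled, with 2 arrays per line and 1 pool of 5 plants behind each array. An inbred line is a stock that breeds nearly true after repeated selfing. The labels describe F7025, F7033 and Cm484 as Flint-Dent lines, F98902 as a Dent line and F2 as a Flint line. The label of F7025 names a bm3 parent. The mutation bm3 lies in the gene of caffeic acid O-methyltransferase, an enzyme of lignin synthesis, and the label does not say whether F7025 carries it. The series set out to find genes of wall formation that bear on how well stem walls are degraded. Between 57.7% and 58.5% of probe sets reached a log2 value of 4 on each array. Across probe sets, which are not independent replicates, the 2 arrays of a line correlated at r = 0.965 (F98902) to 0.993 (F2), and no 2 arrays of different lines above 0.937. The 2 arrays of F98902 differed most, with an SD of the difference of 0.606 log2, against 0.276 to 0.46 in the other lines.

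Several genes with large differences were dim in 1 line and bright in the others, or the reverse. The gene of a proline-rich wall protein, prcw1, read 4.83 ± 0.27 (SD, n = 2) in F7033, and its log2 value fell by 9.17 against the mean of the other lines. HRGP, the gene of a hydroxyproline-rich wall glycoprotein, was bright in F98902 alone, at 9.62 ± 2.98. The alkaline alpha-galactosidase gene AGA1 was bright in F7033 alone, M7 in F2 alone, and the ribosomal protein gene rpl30 was dim in Cm484 alone. The genes of single lines named here are set against the mean of the other 4 lines, and 121 of 235 such gene and line pairs also passed in the pairwise contrast with the nearest line. After a Bonferroni adjustment of the limma F-test, 1039 of 11067 probe sets differed among the lines. At the threshold used elsewhere, 8176 (73.9%) differed among the lines in the F-test. In a fit chosen after seeing the data, without the 3 arrays made from the least RNA (the second arrays of F98902, F2 and Cm484), 4817 did.

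**Figure D1:**
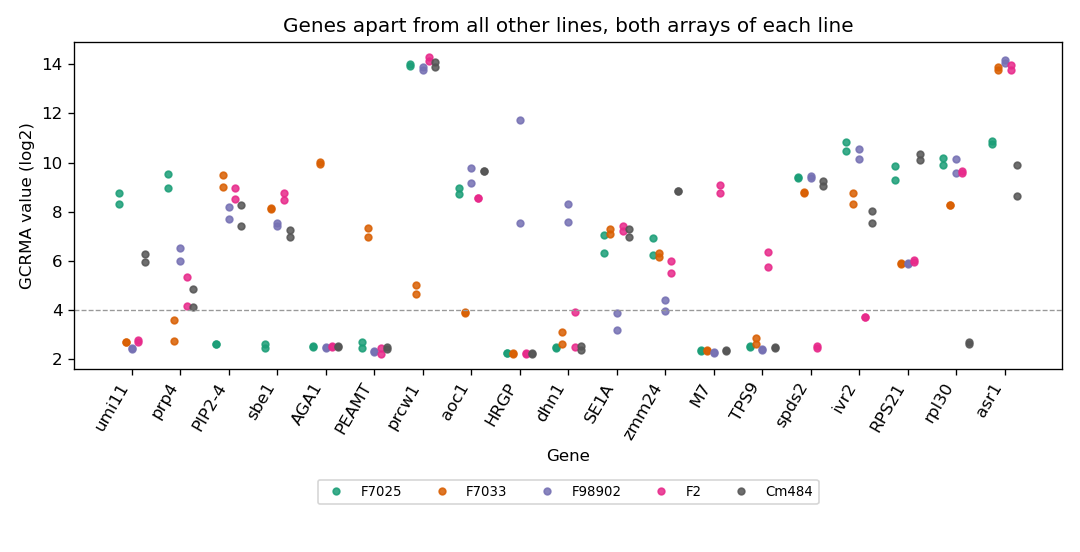
GCRMA values (log2, vertical axis) of 19 genes along the horizontal axis, 1 point per array and 1 colour per line. The 2 points of a line lie close together for most genes, but HRGP in F98902 read 7.52 and 11.73; the dashed line marks the filter at 4.

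Which lines were most alike was read from the 10 pairwise contrasts. F7025 and Cm484 differed least, at 1824 probe sets (16.5%), and their line means correlated at r = 0.932 across probe sets. The other 9 pairs differed at 4114 to 4741 probe sets, with r between 0.856 and 0.876. F7033 and F98902 differed most, at 4741, of which 2453 were higher in F7033 and 2288 lower. F7025 and Cm484 had the fewest calls under every alternative tried, at 967 without F7025 replicate 1, 983 without Cm484 replicate 1 and 818 without Cm484 replicate 2. Without F7033 replicate 1, the count for F7033 and F98902 was 2917. Without any 1 of the 4 arrays of F7033 and F98902, another pair had the most calls.

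**Figure D2:**
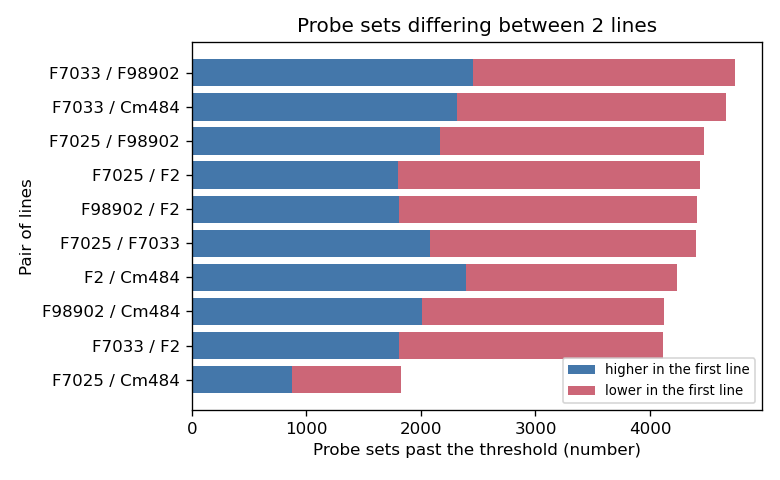
Number of probe sets past the threshold (horizontal axis) for each pair of lines (vertical axis), divided into those higher and those lower in the line named first. The pair F7025 and Cm484, with 1824, has the shortest bar and F7033 and F98902, with 4741, the longest.

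Lignin genes bear on the degradability of stem walls, and 1 pedigree names a brown midrib mutant. The brown midrib gene bm1 (LOC542663), which encodes cinnamyl alcohol dehydrogenase, read between 12.06 and 12.50 on all 10 arrays. Its log2 difference from the mean of the other lines was 0.14 in F7025, −0.11 in F7033, −0.06 in F98902, 0.10 in F2 and −0.06 in Cm484, each with an SE of 0.10. The limma fit put 0 of 5 line contrasts and 0 of 10 pairs past the threshold, and also 0 and 0 at an unadjusted p under 0.05; its F-test gave an adjusted p of 0.516. The sign of these small differences turned without F7025 replicate 1 (−0.04 in F7025) and without F98902 replicate 1 (0.05 in F98902).

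Cm484 had the lowest values of 2 further lignin genes. The cinnamoyl-CoA reductase gene cncr1 read 10.76 ± 0.27 against 11.91 in the other lines, 2.21-fold lower (limma adjusted p = 0.00074), though the difference from F2, the nearest line, did not pass (−0.41, adjusted p = 0.121). The 4-coumarate ligase gene 4CL was 1.63-fold lower (adjusted p = 0.0102), a call lost without Cm484 replicate 1 (adjusted p = 0.125). The phenylalanine ammonia-lyase gene pal3 was 1.22-fold higher in F98902 (adjusted p = 0.0115; 0.0856 without F98902 replicate 2). Of the 4 tested genes of lignin monomer biosynthesis, 3 were higher in F98902, 2 lower in Cm484, 1 higher in F7033 and 1 lower in F2, and the counts adjusted over the list alone were equal. In F7025 limma called 0 of the 4, with 1 at an unadjusted p under 0.05. Among the 3 tested laccases and peroxidases, LAC1 was 2.23-fold lower in F7025. In F2, pox2 was at least 3.84-fold higher and PER42 6.82-fold lower. Calls in this list numbered 1 higher and 2 lower in F7025, 1 and 1 in both F2 and Cm484, and 1 lower in F7033, with equal counts adjusted over the list alone. In F98902 limma called 0 of the 3, with 1 at an unadjusted p under 0.05.

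Of 14 tested cellulose synthases and COBRA-like genes, 7 were higher and 1 lower in F7025 (10 and 1 adjusted over the list alone), with a median log2 difference of 0.54, or 0.27 without F7025 replicate 1. Camera called the list higher in F7025 (adjusted p = 0.0268), but not with an estimated correlation (adjusted p = 0.99 with an estimated correlation) or without F7025 replicate 1 (0.471), nor did fry (0.113). CesA12, a synthase of secondary walls, read 11.92 ± 0.17 against 11.07, 1.81-fold higher (limma adjusted p = 0.00373). Its difference from F7033, the nearest line, did not pass (0.37 log2, adjusted p = 0.179). CesA-5 differed by −0.47 log2 in F7025, or −0.32 without F7025 replicate 2. Its difference from F98902, the nearest line, did not pass (−0.36, adjusted p = 0.0635). In Cm484, 2 were higher and 5 lower (2 and 6 adjusted over the list alone). The secondary wall genes cesa10 and cesa11 were 2.71-fold and 2.18-fold lower there and CesA-4 2.37-fold lower, the last 2 calls being lost without Cm484 replicate 2 (adjusted p = 0.052 and 0.0553). CesA-3 was 1.87-fold lower in F98902 and 1.42-fold higher in Cm484. In Cm484 it was only 0.1 log2 above F7025, the nearest line, which did not pass (adjusted p = 0.571). In F7033, CesA-6 was 2.02-fold lower and CesA-8 3.58-fold lower (0.0823 without F7033 replicate 1), and 2 genes were higher and 3 lower (1 and 3 adjusted over the list alone). In F2, CesA-1 was 1.48-fold lower (0.156 without F2 replicate 1). Counts were 1 higher and 2 lower in both F98902 and F2 (1 and 2, and 1 and 1, adjusted over the list alone). In the limma contrast with the nearest line, cesa10 in Cm484 and CesA-3 in F98902 passed (adjusted p = 0.0167 and 0.0116). Not passing were cesa11 and CesA-4 in Cm484 (adjusted p = 0.0554 and 0.0982), CesA-6 and CesA-8 in F7033 (0.195 and 0.182) and CesA-1 in F2 (0.301).

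Single genes of wall proteins and wall loosening differed by large folds. In F7033, prcw1 (LOC542467) was 578-fold lower (limma adjusted p = 4.55e-09, 2 of 2 probe sets). In F98902, HRGP (LOC542371) was at least 49.3-fold higher (adjusted p = 0.000243, 2 of 2 probe sets). It read 7.52 on the first array and 11.73 on the second, or at least 11.4-fold and 213-fold higher. The arrays of the other lines read 2.21 to 2.26, at the floor, where they hardly vary. The shared spread gave an SE of 0.84 beside an SD of 2.98 in F98902, so this p understates the spread between its pools. Of these 2 structural wall proteins, HRGP passed in F98902 alone, while prcw1 passed in every line, since its value in F7033 lowers the mean that the other lines are set against; counts adjusted over the list alone were equal. The beta-expansin gene expB7 was at least 4.06-fold lower in F2 (adjusted p = 0.000113). The beta-expansin gene expB4 read 7.24 ± 2.14 in F7025, at least 8.05-fold higher (adjusted p = 0.0125), but at least 2.82-fold with an adjusted p of 0.136 without F7025 replicate 1, and at least 23-fold on that array alone. It exceeded Cm484, the nearest line, by 2.41 log2, which did not pass (adjusted p = 0.145). The xyloglucan endotransglycosylase gene xet1 was 1.52-fold lower in F7025 and 1.67-fold higher in F2, with adjusted p = 0.141 without F7025 replicate 1 and 0.0744 without F2 replicate 1. The 9 tested genes of this list numbered 2 higher and 1 lower in F7025, 1 and 2 in F2, and 1 higher in each of F7033, F98902 and Cm484. Adjusted over the list alone, F2 had 1 and 1, limma called 0 in Cm484 with 1 at an unadjusted p under 0.05, and the other counts were equal. Camera called the list in no line (lowest adjusted p = 0.347). Beside these genes stands the spread between pools: the second array of F98902 exceeded the first by a median of 3.45 log2 over the 9 genes, and that of F7025 fell short of the first (−1.48). RGP, a gene of nucleotide sugar metabolism, was 2.86-fold higher in F98902 and 2.41-fold lower in F7033 (0.0594 without F7033 replicate 1). The glucuronyltransferase genes pglcat6 and pglcat8 were 1.83-fold higher in F2 and 2.10-fold lower in Cm484. Of 4 nucleotide sugar and hemicellulose enzymes, 1 was higher and 2 lower in F7033, 1 and 1 in F98902 (2 and 1 adjusted over the list alone), 1 higher in F2 and 1 lower in Cm484. In F7025 limma called 0, with 1 at an unadjusted p under 0.05.

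In F7025, the 8 most raised genes included umi11, prp4 and chn1, known from responses to pathogens, and an aquaporin and a starch gene were near the floor. The smut-induced gene umi11 read 8.52 ± 0.31 (SD, n = 2), at least 16-fold higher than the mean of the other lines (limma adjusted p = 3.48e-07) and 2.43 log2 above Cm484, the nearest line (adjusted p = 9.39e-05). The chitinase gene chn1 was 5.55-fold and the glutathione transferase gene gst2 8.66-fold higher. The pathogenesis-related gene prp4 and sip1, each under 4 in another line, exceeded the nearest line by 2.99 (F98902) and 2.12 log2 (Cm484). The photosynthetic electron flow gene pgr5 and the aquaporin gene NIP2-2 were high in Cm484 too, and exceeded it by 0.79 and 0.94 log2, which did not pass (adjusted p = 0.0737 and 0.0973). The plasma membrane aquaporin gene PIP2-4 read 2.61 ± 0.01, at least 21.8-fold lower, and the starch branching enzyme gene sbe1 2.53 ± 0.15, at least 14.2-fold lower. Lower as well were the prohibitin gene phb3 (at least 7.78-fold), SAG (3.81-fold), the KNOTTED-type gene lg3 (3.40-fold), SRP2B (3.32-fold) and gst3 (2.95-fold), while zmCL2-2 was low in F7025 and Cm484 alike (−0.44 between them, adjusted p = 0.164). The heat shock gene hsp22 was 4.87-fold higher, and the cell cycle genes cycD2 and cdc2 1.96-fold and 1.94-fold lower. The sucrose synthase gene sh1 was 2.02-fold lower, but its difference from Cm484, the nearest line, did not pass (−0.41 log2, adjusted p = 0.0685). In all, 4134 probe sets passed the threshold, 1834 higher and 2300 lower, and 449 stood apart from each of the other 4 lines. Without F7025 replicate 1, 2558 passed.

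Defence, jasmonate and benzoxazinoid genes in F7025 numbered 12 higher and 2 lower of 25 (12 and 4 adjusted over the list alone), and camera called the list higher (adjusted p = 0.0123; adjusted p = 0.99 with an estimated correlation). Their median log2 difference was 0.75. The call was lost without F7025 replicate 1 (0.0614) and without the filter on dim probe sets (0.119), where the median was 0.21. Of 10 tubulins, 6 were higher and none lower (7 and 1 adjusted over the list alone), with tub5 1.89-fold, tua5 1.44-fold and tua4 1.27-fold higher (tua4 0.177 without F7025 replicate 1). Camera called the tubulins higher (adjusted p = 0.0459; adjusted p = 0.99 with an estimated correlation). This call was lost without F7025 replicate 1 (0.27), Cm484 replicate 1 (0.0531), Cm484 replicate 2 (0.0533), F98902 replicate 1 (0.078) or F98902 replicate 2 (0.0555), and under quantile normalization (0.0552). Of 5 MYB, NAC and KNOTTED-type regulators, 4 were lower (4 adjusted over the list alone), among them kn1, 1.38-fold lower. Camera called them lower (adjusted p = 0.0459; adjusted p = 0.915 with an estimated correlation). That call was lost without F7025 replicate 2 (0.0977), Cm484 replicate 1 (0.0531), Cm484 replicate 2 (0.0507), F98902 replicate 1 (0.0577) or F98902 replicate 2 (0.0555). Without the filter both calls were lost (0.0843 for tubulins and 0.449 for regulators), and the median of the regulators moved from −0.61 to −0.14. Tubulins and regulators were also lost with a filter at 6 (0.0513 for both), with array weights (0.0597 for both) and when lists of any size were tested (0.0625 for both), an alternative chosen after seeing the data.

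In F7033, 12 of 22 aquaporins and 11 of 19 photosynthesis genes were higher and 11 of 19 ribosomal protein genes lower. Camera called the 3 lists, but none with an estimated correlation (adjusted p = 0.915, 0.99 and 0.99 with an estimated correlation). AGA1 (LOC606463) read 9.97 ± 0.07 (SD, n = 2), at least 62.9-fold higher than in the other lines (limma adjusted p = 7.34e-09). Higher by at least 8.86-fold was PEAMT, a phosphoethanolamine methyltransferase gene of choline synthesis, and by at least 1.69-fold maf1. The tonoplast aquaporin gene TIP4-1 was at least 7.93-fold higher and 2.73 log2 above F98902, the nearest line (adjusted p = 0.000469). GT1 was at least 4.88-fold higher and 1.16 log2 above F98902 (0.00292), and the iron uptake gene ys1 at least 3.09-fold higher and 1.36 log2 above Cm484 (0.00339). The genes gst18 and PIP2-4, each at the floor in 1 other line, exceeded the nearest line by 0.85 (F7025) and 0.54 log2 (F2), which did not pass (adjusted p = 0.243 and 0.214). Besides prcw1, decreases were found in aoc1, an allene oxide cyclase gene of jasmonate synthesis (at least 34.8-fold, in 1 of 2 probe sets), the TATA-binding protein gene tbp1 (at least 9.46-fold) and the fructokinase gene frk1 (11-fold). Lower as well in F7033 were gst2 (6.85-fold), por1 (6.21-fold, in 1 of 2 probe sets) and the cytokinin response gene crr1 (at least 4.01-fold), while prp4 differed from Cm484 by −1.33 log2, which did not pass (adjusted p = 0.0504). The centromeric histone gene cenH3 was 5.40-fold higher, his1 5.04-fold higher and pcna1 2.73-fold lower. The lipoxygenase gene lox1 was 4.65-fold higher and bx6, of benzoxazinoid synthesis, 5.22-fold lower. In all, 5028 probe sets passed, 2457 higher and 2571 lower, and 1057 stood apart from each of the other 4 lines. Without F7033 replicate 1 the count was 2533, and without F7033 replicate 2 it was 3315.

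Aquaporins in F7033 numbered 12 higher and 3 lower of 22 (13 and 3 adjusted over the list alone), with PIP2-6 0.95 log2 above the nearest line, F98902 (adjusted p = 0.0226). Camera called the list higher (adjusted p = 0.0173; adjusted p = 0.915 with an estimated correlation). Of 19 photosynthesis genes, 11 were higher and none lower (11 and none adjusted over the list alone). The antenna protein gene lhcb5-2 was 2.38-fold, the photosystem II gene PSBQ1 1.73-fold and the photosystem I gene psan1 1.70-fold higher. Camera called this list higher (adjusted p = 0.013; adjusted p = 0.99 with an estimated correlation). Of 19 cytosolic ribosomal protein genes, 1 was higher and 11 lower (1 and 11 adjusted over the list alone), with rpp2a-4 3.57-fold and rps13 1.82-fold lower. Camera called them lower (adjusted p = 0.013; adjusted p = 0.99 with an estimated correlation). These 3 calls held with each array left out. For defence, jasmonate and benzoxazinoid genes, 3 were higher and 10 lower (3 and 10 adjusted over the list alone). The camera adjusted p was 0.069, while fry called the list (adjusted p = 0.00492).

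In F98902, dhn1, opr1, ERF1 and cko2 were among the 8 most raised genes, besides HRGP. The dehydrin gene dhn1 read 7.95 ± 0.51 (SD, n = 2), at least 15.4-fold higher than in the other lines (limma adjusted p = 1.45e-05). The cytokinin oxidase gene cko2 was 10.3-fold, the kinase gene PPCK1 at least 7.55-fold and mfs2 at least 2.82-fold higher, with PPCK1 2.2 log2 above F7033, the nearest line (adjusted p = 0.00598). The arrays of F98902 differed for the other raised genes. ERF1 was at least 11.6-fold higher, from bounds of 7.02 on the first array and 19.3 on the second, and 2.74 log2 above F7033, the nearest line (adjusted p = 0.00966). The 12-oxophytodienoate reductase gene opr1 was at least 9.84-fold higher, from bounds of 5.62 and 17.2, and 2.31 log2 above F7025 (adjusted p = 0.00506). IIG2 was at least 5.55-fold higher, from bounds of 2.39 and 12.9, and 1.54 log2 above F7025, which did not pass (adjusted p = 0.0913). SE1A read 3.53 ± 0.49, at least 8.41-fold lower, and the MADS-box gene zmm24 was 6.37-fold, his1 4.64-fold and PIP1-5 4.24-fold lower. The nitrilase gene NIT2 was at least 3.26-fold and sip1 at least 2.73-fold lower. Low in another line too were gst41 (−0.18 from F2, adjusted p = 0.613) and umi11, which was at the floor in F98902, F7033 and F2 alike. Among list members, gst30 was 7.97-fold, the cell wall invertase gene incw1 4.95-fold and the anthocyanin gene a2 4.79-fold higher. The gibberellin synthesis gene an1 exceeded F2, the nearest line, by 0.66 log2, which did not pass (adjusted p = 0.0642). In all, 4868 probe sets passed, 2286 higher and 2582 lower, and 1063 stood apart from each of the other 4 lines. The 2 pools of F98902 differed most, and without the 3 arrays of least RNA, which include 1 of them, 2083 passed. Of the photosynthesis genes, 2 were higher and 9 lower (2 and 9 adjusted over the list alone). Of the tubulins, 1 was higher and 4 lower (1 and 4 adjusted over the list alone). Camera called neither list in F98902 (adjusted p = 0.195 for both), nor any other. Of these 2 lists, fry called the tubulins (adjusted p = 0.0256) but not the photosynthesis genes (0.067).

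In F2, the 8 genes with the largest decreases all had line means under 4. The spermidine synthase gene spds2 read 2.48 ± 0.05 (SD, n = 2), at least 36.4-fold lower than in the other lines (limma adjusted p = 1.39e-08). Lower too were the thaumatin-like gene pr5 (at least 41.8-fold), the vacuolar invertase gene ivr2 (at least 40.2-fold), pgr5 (at least 29.1-fold), the tonoplast aquaporin gene TIP2-1 (at least 19.3-fold) and HP3 (at least 16-fold). The list ended with gst18 (at least 13.6-fold) and the wound-induced inhibitor gene wip1 (at least 12.9-fold). M7 read 8.92 ± 0.24, at least 30.2-fold higher (adjusted p = 2.71e-08, 2 of 2 probe sets). The ethylene synthesis gene ACO20 was 8.08-fold, bx6 7.79-fold and lg3 6-fold higher. Smaller bounds held for atGRF2 (at least 4.28-fold), TPS9 (at least 4.15-fold) and vp1, the abscisic acid response gene viviparous1 (at least 2.38-fold). The starch gene bt2 was 5.26-fold higher and Agpsemzm 6.09-fold lower, and sbe1, at the floor in F7025, was 0.51 log2 above the nearest line, F7033 (adjusted p = 0.0483). The gene rip2, of a ribosome-inactivating protein, was at least 2.21-fold higher, and the MYB repressor gene myb31 was 0.47 log2 above F98902, which did not pass (adjusted p = 0.124). In all, 4777 probe sets passed, 2816 higher and 1961 lower, and 955 stood apart from each of the other 4 lines. The median difference over all probe sets was 0.10 log2 in F2 and within 0.05 of 0 in the other lines; after median centring, the probe sets differing between F2 and the mean of the other lines were 2318 higher and 2274 lower. Without F2 replicate 1 the count was 2552, without F2 replicate 2 it was 2501, and without the 3 arrays of least RNA 2098.

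Photosynthesis genes in F2 numbered 2 higher and 11 lower of 19 (2 and 12 adjusted over the list alone). Besides pgr5, lhcb5-2 was 3.91-fold and psah1 1.77-fold lower, while psad1 was 2.96-fold higher. Camera called the list lower (adjusted p = 0.00376; adjusted p = 0.99 with an estimated correlation). Aquaporins numbered 4 higher and 12 lower of 22 (4 and 13 adjusted over the list alone), with TIP1-1 11.4-fold and PIP2-2 at least 7.04-fold lower and pip2-5 at least 1.99-fold higher. Camera called them lower (adjusted p = 0.0123; adjusted p = 0.915 with an estimated correlation). Both calls held with each array left out and under median centring. For the MYB, NAC and KNOTTED-type regulators, 4 of 5 were higher and none lower (4 and 1 adjusted over the list alone). The camera adjusted p was 0.195, while fry called the list (adjusted p = 0.00015). For defence, jasmonate and benzoxazinoid genes, 7 were higher and 9 lower (8 and 11 adjusted over the list alone). The camera adjusted p was 0.188, while fry called the list (adjusted p = 0.00717).

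In Cm484, 9 of 19 cytosolic ribosomal protein genes were higher and 1, rpl30 (LOC541668), was lower (13 and 1 adjusted over the list alone). Camera called the list higher (adjusted p = 0.013), but not with an estimated correlation (adjusted p = 0.99 with an estimated correlation) or without Cm484 replicate 1 (0.055), nor did fry (0.259). The gene rpl30 read 2.64 ± 0.06 (SD, n = 2), at least 43.4-fold lower than in the other lines (limma adjusted p = 7.98e-08), while RPS21 read 10.22 ± 0.16. The MADS-box gene zmm24 was 9.01-fold and the flavanone hydroxylase gene fht1 at least 2.86-fold higher. The aquaporin gene NIP3-1 exceeded F7033, the nearest line, by 0.87 log2 (adjusted p = 0.0286). Several other genes highest in Cm484 did not pass against the nearest line. Over F7025 these were RPS21 (0.64 log2, adjusted p = 0.0504), the replication gene pcna2 (1.16, 0.188), the lysine breakdown gene lkrsdh1 (0.76, 0.121) and the sucrose phosphatase gene spp2 (0.45, 0.251). Likewise PIP2-2 was 1.02 log2 over F7033 (0.0902) and the polyamine oxidase gene mpao1 0.77 over F2 (0.199). The stress and ripening gene asr1 was 14.7-fold lower (2 of 2 probe sets), from 9.57-fold on the first array and 22.6-fold on the second. Lower too were an1 (6.86-fold), lox1 (5.49-fold), glct1 (4.52-fold) and the kinesin gene KIN6 (2.96-fold), and TLA1 was under 4 in 2 other lines too. The gene gst10 differed from F7025 by −1.09 log2, which did not pass (adjusted p = 0.0592), and IIG2 was under 4 in F7033 and F2 as well as Cm484. In all, 4083 probe sets passed, 2032 higher and 2051 lower, and 348 stood apart from each of the other 4 lines. The count was 2072 without Cm484 replicate 1, 2266 without Cm484 replicate 2 and 1469 without the 3 arrays of least RNA.

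**Figure D3:**
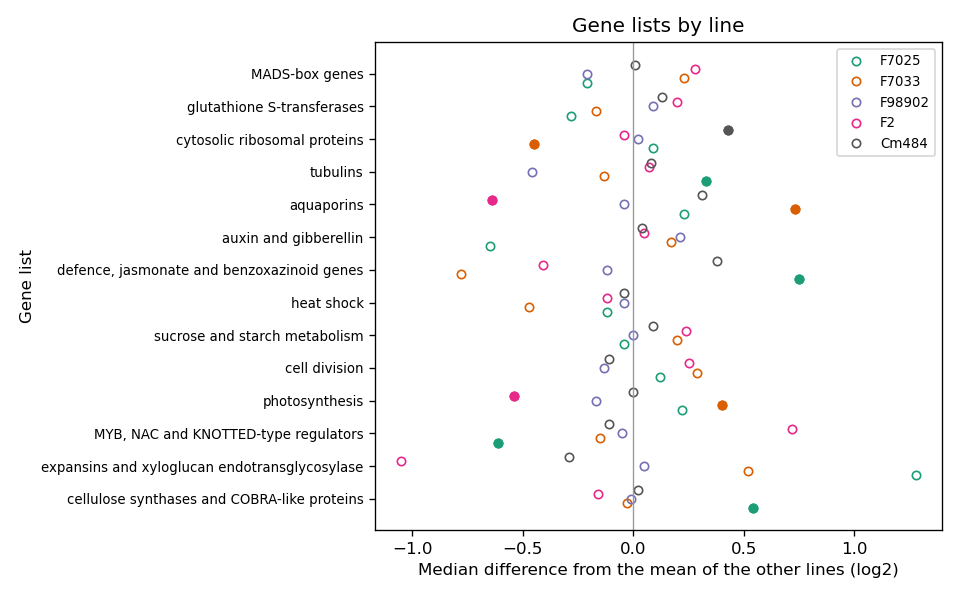
Median log2 difference of each gene list (vertical axis) between a line and the mean of the other lines (horizontal axis), 1 circle per line. Filled circles mark the 10 list and line pairs called by camera at the preset correlation; photosynthesis genes and aquaporins lie right of 0 in F7033 and left of 0 in F2, each of which is part of the mean that the other is set against.

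Genes of cell division, sugar metabolism and flower development differed between lines, and camera called none of these lists in any line. Fry called cell division genes in F7025, F7033 and F98902 (adjusted p = 0.028, 0.0034 and 0.0256). It called MADS-box genes in the same lines (adjusted p = 0.0223, 0.017 and 0.0118), and sucrose and starch genes in no line (lowest adjusted p = 0.0787). Of 17 cell division genes, 5 were higher and 1 lower in F7033, 1 and 5 in F7025, 2 and 5 in F98902, 4 and 2 in F2 and 3 and 4 in Cm484 (3 and 2 in F2 adjusted over the list alone, the others equal). Among them, his1a was 2.24-fold higher in F2. Of 20 sucrose and starch genes, 6 were higher and 5 lower in F7025, 4 and 4 in F7033, 6 and 7 in F98902, 8 and 4 in F2 and 5 and 3 in Cm484. Adjusted over the list alone, F98902 had 6 and 9 and Cm484 5 and 5, the others being equal. The starch gene Agpsemzm was 2.47-fold higher in F7033 and the sucrose phosphatase gene spp1 2.26-fold lower in F98902. Agpsemzm in F7033 was 0.44 log2 above Cm484, the nearest line, which did not pass (adjusted p = 0.07). Of 11 MADS-box genes, 4 were lower in F7025 and 4 higher in F7033, while F98902 had 1 higher and 5 lower, F2 6 and 2 and Cm484 5 and 2 (7 and 2 in F2 adjusted over the list alone, the others equal). The MADS-box gene m4 was 1.95-fold lower in F7025 and 1.58-fold higher in F7033, and zap1 was 1.83-fold higher in F7033 and 1.82-fold lower in F98902. Against the nearest line, only m4 in F7025 passed (−0.7 log2 from Cm484, limma adjusted p = 0.00994). In F7033, m4 was 0.3 log2 above F2 (adjusted p = 0.113) and zap1 0.33 above Cm484 (0.0706). In F98902, zap1 differed from F7025 by −0.28 (0.117).

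Glutathione transferase, heat shock, hormone and flavonoid genes likewise went both ways, and camera called none of these lists that were large enough to test. Fry called glutathione S-transferases in F7025 and F2 (adjusted p = 0.0374 and 0.019) and auxin and gibberellin genes in F7025 (adjusted p = 0.0374). It called heat shock genes in no line (lowest adjusted p = 0.0748). Of 13 glutathione S-transferases, 5 were higher and 4 lower in F7025, 4 and 3 in F7033, 3 and 4 in F98902, 6 and 4 in F2 and 2 and 4 in Cm484. Adjusted over the list alone, F7025 had 5 and 6 and Cm484 3 and 4, the others being equal. GST39 was 2.98-fold higher in F7033 and 2.83-fold lower in F98902. The gene gst19 was 3.52-fold lower in F2, but its difference from Cm484, the nearest line, did not pass (−0.44 log2, adjusted p = 0.0696). Of 7 heat shock genes, 2 were higher and 2 lower in F7025, 1 and 3 in F7033, 1 and 1 in F98902, 3 and 2 in F2 and 2 and 1 in Cm484 (2 and 3 in F7033 adjusted over the list alone, the others equal). The chaperone gene hsp70-5 was 1.67-fold lower in F7033 and 1.75-fold higher in F2. In F2 it was 0.17 log2 above F98902, the nearest line, which did not pass (adjusted p = 0.177). Of 7 auxin and gibberellin genes, 2 were higher and 3 lower in F7025, 3 and 1 in F7033, 3 and 2 in both F98902 and F2, and 1 and 1 in Cm484 (2 and 4 in F7025 adjusted over the list alone, the others equal). The auxin-binding protein gene abp1 was 2.70-fold lower in F7033, but its difference from F2, the nearest line, did not pass (−0.44 log2, adjusted p = 0.161). Of 3 flavonoid and anthocyanin genes, 1 was higher and 2 lower in both F7025 and F98902, 1 was lower in F7033 and in F2, and Cm484 had 1 and 1 (1 and 2 in Cm484 adjusted over the list alone, the others equal). Of 24 pollen, tassel and seed genes only 1 reached the filter, and limma called it in 0 lines, with 0 at an unadjusted p under 0.05.

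Across all lists, camera called 10 of 70 list and line pairs. With an estimated correlation, camera called 0, with 3 at an unadjusted p under 0.05, and fry called 25, among them 8 of the 10, all but the cellulose synthases in F7025 (adjusted p = 0.113) and the ribosomal proteins in Cm484 (adjusted p = 0.259). The estimated correlation was −0.176 for the MYB, NAC and KNOTTED-type regulators and 0.0146 for aquaporins, against the preset of 0.01. For the other called lists it ran from 0.0756 (defence genes) to 0.774 (ribosomal proteins). A clearly higher correlation thus cannot account for the lost calls of aquaporins and regulators. The lowest unadjusted p of camera with an estimated correlation was 0.0206 over the 70 pairs. Its lack of calls therefore gives no evidence on whether the genes of any single list are correlated. Median, mean and test of a list differed in sign for 21 of the 70 pairs and for 0 of the 10 called. The 21 were found in cellulose synthases (F98902, Cm484), MYB, NAC and KNOTTED-type regulators (F98902), defence genes (F98902), auxin and gibberellin (Cm484) and tubulins (F7033, Cm484). The others were in cell division (F7025, F2, Cm484), sucrose and starch metabolism (F7025, F98902, F2), heat shock (F7025, F98902, F2, Cm484) and glutathione S-transferases (F7025, F7033, F98902, F2).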

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

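The fits without the reporter controls and without the 3 arrays of least RNA, and the tests of lists of any size, were chosen after seeing the data. Of 240 gene results, 8 were no longer past the threshold with array weights, 7 with a floor at 4, 6 without the filter, 2 each without the variance trend, with median centring and with quantile normalization, and 1 with the replicate number as a block. None changed with the robust prior or without the reporter controls, nor any of the 210 that a filter at 6 leaves. With that block, 8069 probe sets differed among the lines and 8 lists were called. The labels give no batch or day behind the replicate number. Deviations of equally numbered arrays correlated over 0.1 in 5 of 10 pairs of lines, most among F98902, F2 and Cm484 (0.269 to 0.375), whose second arrays had the least RNA, and at −0.381 between F7025 and F98902. Deviations shared by number in part of the lines thus remain in the fit without the block. Between 1 and 8 of the 240 gene results could not be recomputed when an array was left out, since the gene no longer passed the filter, as HRGP in F98902.

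Leaving out 1 array leaves a line with 1 array, assumed to vary like the others. The F-test count then ranged from 6680 to 8443. Against the mean of the other lines the ranges were 2558 to 4484 in F7025, 2533 to 5321 in F7033, 3331 to 4900 in F98902, 2501 to 5180 in F2 and 2072 to 4544 in Cm484. Between F7025 and the others they were 2632 to 4809 (F7033), 3458 to 4146 (F98902), 2721 to 4928 (F2) and 818 to 2268 (Cm484). Between F7033 and the others they were 2917 to 4972 (F98902), 2446 to 4565 (F2) and 2813 to 5090 (Cm484). The remaining ranges were 2683 to 4624 (F98902 and F2), 2604 to 4332 (F98902 and Cm484) and 2590 to 4638 (F2 and Cm484). The lowest count came without an array of a compared line, which leaves fewer arrays. List calls ranged from 7 to 11.

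Without the 3 arrays of least RNA, counts fell to 4817 among the lines, 2083 in F98902, 2098 in F2 and 1469 in Cm484. For pairs they were 2656 (F7025 and F98902), 2662 (F7025 and F2), 596 (F7025 and Cm484), 2598 (F7033 and F98902), 2272 (F7033 and F2) and 2864 (F7033 and Cm484). The last were 1477 (F98902 and F2), 1715 (F98902 and Cm484) and 1713 (F2 and Cm484), and 41 of 228 gene results were lost. This fit has fewer arrays, so it does not show that the RNA amount was the reason. On the 4 arrays of 2 lines alone, F7025 and F98902 differed at 2446 probe sets and F7025 and Cm484 at 1057.

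Without the filter, F98902 had 8815 calls, 2541 higher and 6274 lower. Of these, 4885 passed the filter of the reported fit and 3930 were under it, 3683 of them lower. Among all 6554 probe sets under the filter, the 2 arrays of F98902 had the lowest medians of the 10, 2.21 and 2.20, so the added calls lie at the floor of the array. Probe sets apart from each of the other 4 lines numbered 449 in F7025, 1057 in F7033, 1063 in F98902, 955 in F2 and 348 in Cm484, a narrower question by construction. Array signal over that floor limits what can be told of dim genes.

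Of the 10 list calls, camera with an estimated correlation made 0, with 3 at an unadjusted p under 0.05. The defence list in F7025 was lost without the filter (0.119). The tubulins and the MYB, NAC and KNOTTED-type regulators in F7025 were lost without the filter (0.0843 and 0.449), with a filter at 6 (0.0513 for both), array weights (0.0597 for both), the replicate block (0.053 for both) and without the 3 arrays of least RNA (0.0585 and 0.0554). Tubulins were also lost with quantile normalization (0.0552). With lists of any size, 8 of 105 list and line pairs were called, none with fewer than 5 genes, and both were lost (0.0625 for both), since more pairs enter the adjustment. For bm1, which passed nowhere, the difference in F7025 ranged from −0.04 to 0.31 as arrays were left out. In F98902 it ranged from −0.17 to 0.05, the latter without F98902 replicate 1, and the cause was not tested.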

Other observations

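The tests on the 2 arrays of F98902 were chosen after the result was seen, the others before. A random pairing of the arrays can be excluded as the source of the number of probe sets that differed among the lines. Of 100 groupings of the 10 arrays into 5 pairs, drawn from 945, 1, the real one, gave as many (8176). The highest other gave 4922 and kept 3 of the real pairs. The test shows that the 2 arrays of a line are alike. It cannot tell differences between lines from technical ones that both pools of a line share.

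Several genes named above were near the floor in 1 line and bright in the others, as spds2 in F2, rpl30 in Cm484 and tbp1 in F7033. A technical reading is that a line carries sequence variants under the probes, so that its RNA binds poorly. A second probe set of the same gene would then show a smaller decrease. For probe sets lower in 1 line than in each other line, the median ratio of the second to the called difference was 0.728, against 0.835 on the higher side. The lower side held 54 pairs of a called and a second probe set, from 33 genes (bootstrap interval over pairs 0.442 to 0.827). Where both probe sets were called, the pair entered in both orders, which can draw the median upwards, and the interval treats pairs as independent. Of the 54 ratios, 26 were over 0.75 and 16 under 0.25, 7 of these in the opposite direction. On the higher side, 40 of 70 were over 0.75 and 13 under 0.25. The median of the lower side lay under the bound of 0.75 set beforehand for excluding variants, and its interval spans that bound. Sequence variants and lower transcript levels thus cannot be told apart here, and variants may explain part of these decreases. The genes spds2, rpl30 and tbp1 had 1 tested probe set each, so this test does not cover them.

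F7025 and Cm484 differed at the fewest probe sets. A candidate explanation is chromosome segments shared by descent, in which neighbouring genes would be alike or different together. The called state of neighbouring genes correlated at 0.049 over 706 neighbour pairs, with a one-sided permutation p of 0.096 over 10000 shuffled orders and an adjusted p of 0.48 over the 10 pairs. With 784 placed genes the value lay below 0.062, the value that shuffled orders reach at a one-sided p of 0.05, and under the bound of 0.05 set beforehand, but under that bound by less than the SD of the shuffles (0.038), so the question stays open. The condition that the value be read with its spread was added after the value was seen. The pedigrees in the labels name no shared parent for these 2 lines.

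The 2 arrays of F98902 differed more than those of any other line. RNA degradation in the second array would lower the 5' signal of control transcripts against the 3' signal. That array was below all 9 others for 2 of 3 controls, elongation factor 1-alpha (−2.69 against −2.19 at the lowest) and GAPDH (−2.30 against −2.06), but not for cyclophilin (−0.62). More growing tissue in the second pool is the other candidate explanation. The expansin list rose by a median of 3.45 log2 from the first array to the second, at percentile 100 among 10000 random lists. No other tested list rose as much in F98902, the next being cellulose synthases at 0.5. Genes of the expansin list vary together (estimated correlation 0.516), while random lists were drawn gene by gene. The percentile is therefore overstated and gives no independent support. Cell division genes, which growing tissue would also raise, stood at percentile 71 with a median of 0.01, and neither explanation could be excluded.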
